A study of Thunnus thynnus with 30 samples.

How the data were processed

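Whole larvae of Atlantic bluefin tuna (Thunnus thynnus) were measured by RNA sequencing after feeding on rotifers (Brachionus rotundiformis, small live prey) that carried 1 of 3 levels of docosahexaenoic acid (DHA, a long-chain omega-3 fatty acid). Per the labels, rotifers held 2, 3.6 or 10.9 mg DHA per g dry weight, called low, medium and high here, larvae were kept in 3 tanks per treatment, and samples came from ages of 5, 10 and 15 days after hatching (dph). The deposited table holds raw counts per gene name, as whole numbers with no missing values; the authors' notes name DESeq2 without a version. The aligner, the counting program, the assembly and the annotation are not given in the sources used here, and neither is what was summed to make the table. A second deposited table pairs titles with library numbers and was not used as a measurement.

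The table has 7295 rows and 26 libraries in 9 groups of age and DHA level. Totals ran from 12805866 to 19169404 counts per library, the median row had a mean of 549 counts, and the lowest row total was 21. Names were used as the table gives them. Differing only in capitals, 454 names were shared by 916 rows, and such rows were kept apart, so 1 gene's reads can stand in more than 1 row. No coordinates come with the table, and 4404 names matched a symbol of the reference gene list, which was too few for a check on gene length or GC content from the annotation. The 4 internal control samples have no column in the count table and were not analysed here, so the planned result on them was not run. The 5 dph high DHA library with title number 3 carries sample number 1 in its treatment label; the title number was used, and the other number was tried as an alternative.

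Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows were filtered with filterByExpr on the 9 groups (7292 tested, 3 removed), libraries were scaled by TMM, and each group had its own mean. Genes were tested by the quasi-likelihood F-test with robust estimation, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The comparisons were high with low, medium with low and high with medium DHA at each age, high with low averaged over ages, 10 with 5 and 15 with 10 dph averaged over DHA levels, the change of the high to low difference between ages, and a trend per doubling of rotifer DHA with age as a factor. Log2 fold changes are given with a standard error computed from the F statistic; levels are CPM, counts scaled by library size, with the SD between libraries. The common biological coefficient of variation was 11.9%. Replicates are labelled as tanks; p measures the spread between the sampled libraries.

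Before the data were examined, 29 lists of genes with known functions were fixed, covering lipid metabolism, sense organs, digestive organs, muscle, skeleton, nervous system, cell growth, stress, endocrine, immune, blood, skin and clock genes. They hold 725 rows, and 28 lists had at least 5 members and were tested as sets. For each list, member counts are given over all genes and adjusted over the list alone. List members are rows, called genes here, so names that differ only in capitals, such as GRIA1 and Gria1, are counted separately. Sets were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with fry. None of the camera calls in any high with low comparison or age comparison held with an estimated correlation. Fry called 0, 5 and 14 lists for high with low at 5, 10 and 15 dph. It called 6 for the average, and 17 and 19 for the ages. For medium with low it called 5, 11 and 0, and for high with medium 0, 2 and 8.

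Named genes were taken by a rule fixed in advance. For high with low and for the ages, these were the 8 largest rises and 8 largest falls among changed genes of at least 5 CPM. For high with low within an age, the libraries of the compared groups also could not overlap. For the average and the age comparisons, the averaged differences instead had to have the same sign, so libraries can overlap. For trends and changes between ages, the 5 smallest p in each direction were taken. For comparisons with medium DHA, 3 in each direction were taken, and up to 4 members of each list. Where fewer passed, all were eligible, and where none passed the 3 smallest p were taken. Any other gene is said to be chosen after its values were seen. A few genes that the rule took are not reported here.

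The fits were tested on simulated data of the same design, 7292 genes of which 200 were changed. Each simulated library was drawn independently, so structure shared between libraries was not tried. False calls among unchanged genes numbered 5 to 14 per comparison. The test recovered 45% of 1.5-fold and 93% of 2-fold changes for high with low at 5 dph, and 69% and 96% at 10 dph. For the average over ages it recovered 95% and 99%, for 10 with 5 dph 93% and 100%, for the change between 10 and 15 dph 36% and 83%, and for the trend 88% and 99%.

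Alternatives fixed in advance were DESeq2 1.42.0 with its Wald test, DESeq2 size factors in edgeR, a mean CPM of at least 10, no filter, an absolute log2 fold change of at least 1, a fit to the compared groups alone, an additive model, a linear DHA scale, replicate numbers as a block and leaving out each library in turn. Whether replicate numbers pair the samples was checked on residual correlations. Among pairs of groups, 37 of 100 same-number library pairs exceeded a correlation of 0.1 with a median of 0.053, against 45 of 200 different-number pairs with a median of -0.024. Of same-number pairs within 1 DHA level, which can share a tank, 11 of 25 exceeded 0.1 (median 0.081). Within 1 age 12 of 25 did (median 0.062), and 12 of 26 libraries correlated best with a library of their own number. Some pairing by number thus stays possible. The planned fit had no block, and the block was kept as an alternative.

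After the data were seen, more measures and alternatives were added. One was a length score per library, the mean log2 CPM of 52 very long genes, from a textbook list of 70, less that of 153 short genes of the respiratory chain and ribosome; it was used as a covariate. Another was a set of 64 prey-like rows, low-count rows whose levels followed those of 16 ribosomal protein rows with fly-style names (correlation of at least 0.9); counts were repeated without them. Counts were also repeated without the 2 libraries of lowest TMM factor and with 1 row kept of each set of identical rows, and the lists were also tested in comparisons with medium DHA.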

Results

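RNA from whole bluefin tuna larvae was sequenced to ask how the DHA content of rotifer prey bears on larval development and growth. Larvae fed low, medium or high DHA were sampled at 5, 10 and 15 dph, giving 26 libraries in 9 groups of 3, except for high DHA at 5 dph, which had 2 (replicates 2 and 3). Totals were 12805866 to 19169404 counts per library, spread over 7292 tested genes. In a principal component analysis the first component held 53.2% of the variance and the second 17.9%. Mean scores on the first component were -37.8 for low DHA at 5 dph and 28.2 at 15 dph. At 10 dph low DHA stood apart, at 18.3 ± 4.11 on the first component (SD, n = 3) against -5.5 ± 7.48 for medium and -3.37 ± 3.67 for high DHA.

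**Figure D1:**
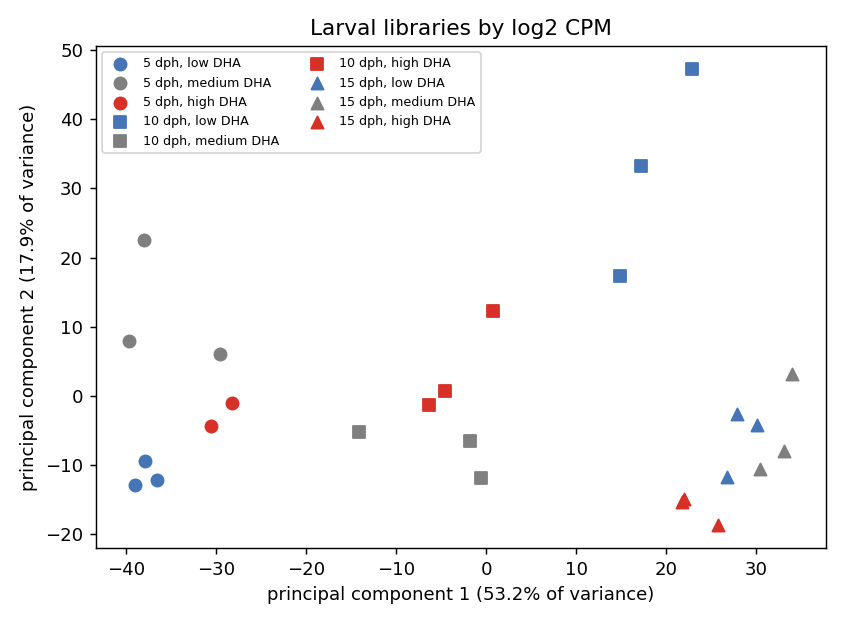
Scores of the 26 libraries on the first (53.2% of variance, horizontal) and second (17.9%, vertical) principal components; colour gives the DHA level and shape the age. On the second axis the 10 dph low DHA libraries averaged 32.6 ± 15 (SD, n = 3).

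Long and short transcripts differed in their balance between libraries. Very long genes stood lower relative to short respiratory chain and ribosomal genes in 10 dph low DHA, with a length score of -4.22 ± 0.5 (SD, n = 3) against -3.45 ± 0.17 for medium and -3.56 ± 0.21 for high DHA. At 5 dph the lowest score was that of medium DHA, -4.14 ± 0.47, against -3.19 ± 0.13 for low and -3.59 ± 0.05 (n = 2) for high. At 15 dph scores were -3.06 ± 0.11, -3.26 ± 0.15 and -2.97 ± 0.12 for low, medium and high DHA. The lowest single libraries were 10 dph low replicate 2 (-4.74) and 5 dph medium replicate 2 (-4.59), which also had the lowest TMM factors, 0.861 and 0.808.

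**Figure D2:**
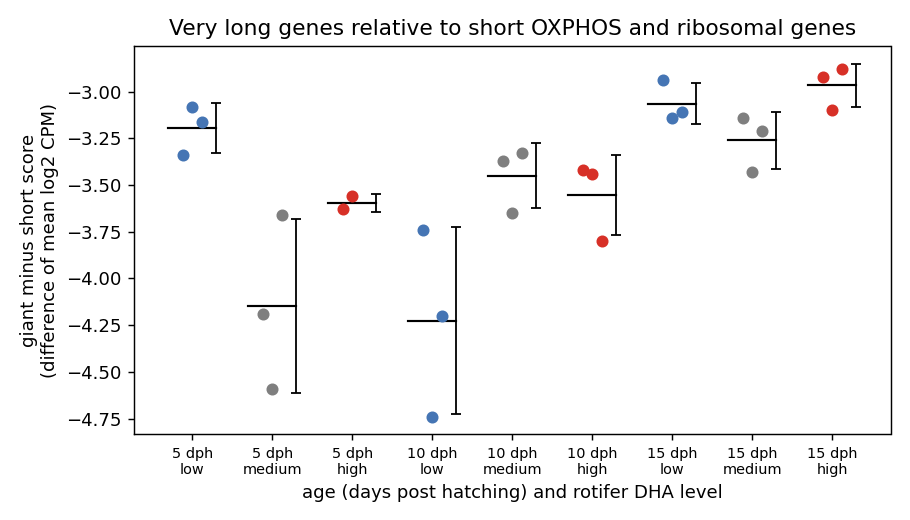
Length score of each library (vertical; mean log2 CPM of very long genes less that of short genes) by age and DHA level; points are libraries, the line is the group mean and the bar 1 SD. The 10 dph low DHA group averaged -4.22 and the 5 dph medium DHA group -4.14.

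A set of 64 low-count prey-like rows, many with ribosomal protein names, also varied between groups. They summed to 210 ± 43.7 CPM (SD, n = 3) in low, 214 ± 128 in medium and 88.7 ± 1.54 (n = 2) in high DHA at 5 dph. At 10 dph the sums were 4.8 ± 4.88 in low, 61.9 ± 16.1 in medium and 56.3 ± 19.9 in high DHA. On the log scale high and medium DHA each differed from low with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows; the lowest library was low replicate 3, at 0.821 CPM. At 15 dph the sums were 7.45 ± 4.84, 3.28 ± 0.93 and 12.6 ± 11.2 CPM. Because of these rows, 39 of the 121 ribosomal protein rows are described apart from the other 82.

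**Figure D3:**
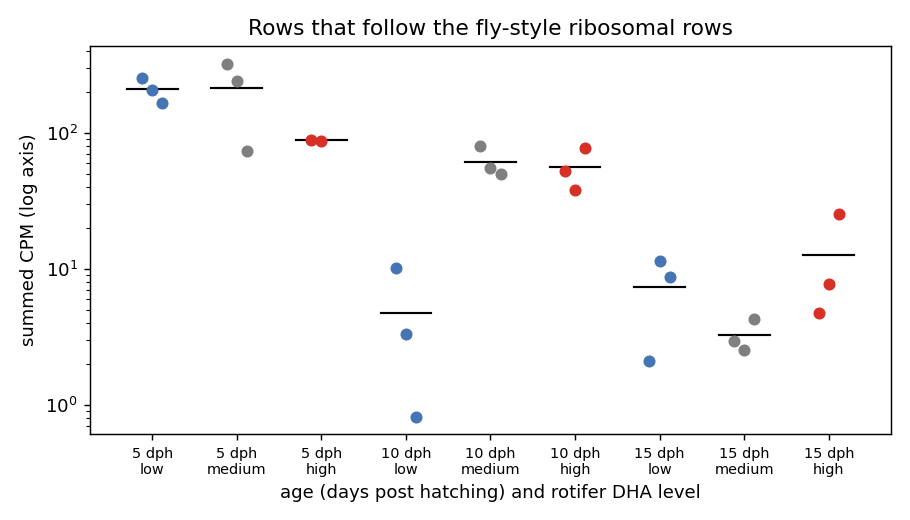
Summed CPM of the 64 prey-like rows in each library (vertical, log axis) by age and DHA level; points are libraries and the line is the group mean. The 10 dph low DHA group averaged 4.8 CPM, and 10 dph medium and high DHA averaged 61.9 and 56.3 CPM.

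To ask what high DHA changed in the youngest larvae, high was compared with low DHA at 5 dph. Of 6 changed genes 4 were higher in high DHA, among them NOP58 and NLE1, which serve ribosome assembly, and IFRD1, a transcriptional coregulator. IFRD1 rose from 49.1 ± 0.204 CPM (SD, n = 3) to 75.6 ± 0.272 (n = 2), a log2 fold change of 0.62 ± 0.1 (SE, adjusted p = 0.0048), and NOP58 rose by 0.47 ± 0.09 (adjusted p = 0.025). NLE1 rose by 0.58 ± 0.11 and cetA by 0.99 ± 0.15. ABRA, an actin-binding muscle protein gene, fell from 32.8 ± 2.49 to 17.1 ± 0.389 CPM (log2 fold change -0.94 ± 0.17, adjusted p = 0.017), and NFE2L1, a transcription factor of proteasome genes, changed by -0.85 ± 0.15 (adjusted p = 0.014).

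None of the 22 sterol synthesis genes passed at 5 dph over all genes, but 18 were higher adjusted over the list alone, with a median log2 fold change of 0.48. FDPS stood at 0.96 ± 0.22 (adjusted p = 0.08) and NSDHL at 0.83 ± 0.24 (adjusted p = 0.2). Camera called this list (adjusted p = 1.3e-15, and adjusted p = 0.46 with an estimated correlation). Fry called 0 of the 28 lists in this comparison. Camera also called 6 other lists, none with a member that passed. Higher were respiratory chain (median 0.17), cell cycle (0.17), heat shock (0.16) and liver genes (0.14), and lower were neuron (-0.19) and fast muscle genes (-0.17); for each of these the adjusted p was 0.7 with an estimated correlation. The mean length score was -3.59 in high and -3.19 in low DHA, and with it as a covariate the medians of respiratory chain and neuron genes were 0.01 and 0.02. Those of cell cycle, heat shock, liver and fast muscle genes were 0.22, 0.08, 0.13 and -0.18. The score is built in part from the respiratory chain genes, and the sterol median was 0.52 with it. Without 5 dph low replicate 2 or 3 there were 2 changed genes each, and without high replicate 2 or 3 there were 0 and 1, a lone high library then being assumed to vary like the other groups. At unadjusted p under 0.05 there were 790 genes, DESeq2 called 44, and a fit to the compared groups alone called 1951.

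At 10 dph 1737 genes changed between high and low DHA, 1417 higher and 320 lower in high DHA. PDK2, a kinase that restrains pyruvate oxidation, rose from 64.4 ± 16.2 to 244 ± 79.8 CPM (SD, n = 3; log2 fold change 1.92 ± 0.37, SE, adjusted p = 0.0023), and LPIN1, a phosphatidate phosphatase, rose by 1.37 ± 0.24 (adjusted p = 0.0016). FKBP5, a co-chaperone induced by glucocorticoids, rose from 63.7 ± 16.4 to 156 ± 41.7 CPM (1.29 ± 0.24, adjusted p = 0.0019). The muscle giant NEB (1.99 ± 0.5) rose, as did klhl38 (1.78 ± 0.36), ubald2 (1.69 ± 0.34) and the decoy receptor Il1r2 (1.67 ± 0.35). Among the genes named here TRIM16 and Trim25 had the largest rises, 4.43 ± 0.97 and 4.03 ± 0.91, but belong to a large gene family whose reads can be split between rows. Falls included Aqp8, a water channel (-1.73 ± 0.46), G0s2, an inhibitor of fat breakdown (-1.61 ± 0.45), hsp70 (-1.48 ± 0.43) and cyp26a1, which degrades retinoic acid (-1.21 ± 0.29, adjusted p = 0.0064).

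Of 40 neuron and synapse genes 27 rose at 10 dph, 1 fell and the rest did not pass (29 and 1 adjusted over the list alone). Examples are the synaptic vesicle genes Sv2a (0.65 ± 0.14) and SYT1 (0.55 ± 0.12) and the GABA receptor subunit GABRB2 (0.73 ± 0.16). Camera called the list at adjusted p = 5.2e-07, and the adjusted p = 0.81 with an estimated correlation. These genes moved with the length score, and with that score as a covariate none of the 40 passed and the median went from 0.57 to 0.13. Lens genes moved the other way: 7 of 14 fell (11 adjusted over the list alone), among them CRYBA1 (-1.01 ± 0.29), CRYBA2 (-0.8 ± 0.24) and BFSP2 (-1.05 ± 0.27), with camera adjusted p = 0.00021 and adjusted p = 0.81 with an estimated correlation. With the score none of the 14 passed, but their median only went from -0.7 to -0.46. Of 121 ribosomal protein rows 29 rose and 2 fell (37 and 3 adjusted over the list alone); of the 82 that are not prey-like 0 rose and 2 fell by edgeR.

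Endocrine and clock genes changed as well at 10 dph. Of 18 growth and endocrine genes 8 rose and 2 fell (8 and 2 adjusted over the list alone), including Hsd11b2, which inactivates cortisol (0.81 ± 0.16), the receptor gene Igf1r (0.71 ± 0.17) and the insulin gene ins (-0.58 ± 0.12, adjusted p = 0.003). Of 16 clock genes 8 rose and 1 fell (8 and 2 adjusted over the list alone), including NR1D1 (1.21 ± 0.29), TEF (1.16 ± 0.26), Bhlhe41 (1.08 ± 0.24) and HLF (1.06 ± 0.24). Of 26 phototransduction genes 7 rose and 1 fell (8 and 3 adjusted over the list alone), with the arrestins sag (1.17 ± 0.27) and ARR3 (0.85 ± 0.2) among them. Camera called none of these lists. In lipid metabolism few members passed: 3 of 18 fatty acid oxidation genes rose, with CPT1A at 0.34 ± 0.09, and of 22 sterol genes 1 rose and 1 fell (NSDHL, -0.6 ± 0.2; 1 and 0 adjusted over the list alone). Of the list for long-chain polyunsaturated fatty acid synthesis 1 of 9 rose (HACD2, 0.25 ± 0.08), and the desaturase fads2 stood at 0.16 ± 0.13 (adjusted p = 0.39). Of 52 cell cycle genes 5 fell (1 adjusted over the list alone; median -0.16; camera adjusted p = 0.0052, and adjusted p = 0.81 with an estimated correlation). No respiratory chain gene passed (median -0.16; camera adjusted p = 5.2e-07, and adjusted p = 0.81 with an estimated correlation). As a covariate the length score left 1 growth and endocrine gene that rose, and no member of the clock, phototransduction or other lists of this paragraph passed. The median went from 0.15 to 0.02 for clock and 0.13 to 0.04 for phototransduction genes. For respiratory chain genes it went from -0.16 to 0.11, but the score is built in part from these genes, so they cannot be judged with it. The median stayed nearer for growth and endocrine (0.18 and 0.11), sterol (-0.07 and -0.08) and cell cycle genes (-0.16 and -0.15), so the lost calls alone do not tie these 3 lists to the score.

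With the length score as a covariate, 71 genes changed at 10 dph, 70 of them among the 1737. Of these 71 genes 17 were ribosomal protein rows, all of them higher. Without the score 0 of the 82 ribosomal rows that are not prey-like rose. How many of the 71 were prey-like was not counted. With 10 dph low replicate 2 and 5 dph medium replicate 2 left out there were 678 changed genes. Without 10 dph low replicate 2 or 3 there were 428 and 991 genes, and without high replicate 1 or 2 there were 911 and 618. Of the 1737 changed genes 50 were prey-like rows.

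At 15 dph 544 genes changed between high and low DHA, 218 higher and 326 lower, and sterol synthesis was lower in high DHA. Of 22 sterol genes 19 fell (21 adjusted over the list alone), with a median of -0.61. IDI1 was at 377 ± 49.7 CPM in low, 284 ± 17.4 in medium and 196 ± 24 in high DHA (SD, n = 3; high over low -0.95 ± 0.13, SE, adjusted p = 0.00032). The gene dhcr7, whose enzyme makes cholesterol from its last precursor, was at 212 ± 41.2, 191 ± 19.1 and 116 ± 9.55 CPM (-0.88 ± 0.15, adjusted p = 0.0014), and Hsd17b7 fell by 0.62 ± 0.12 on the log2 scale. Camera called the list (adjusted p = 1.4e-16; adjusted p = 0.13 with an estimated correlation), and fry gave adjusted p = 0.0011. With the length score as a covariate 19 members still fell.

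Fat synthesis and lipid handling genes were lower in high DHA at 15 dph too. Of 14 lipogenesis genes 6 fell (8 adjusted over the list alone), including ME1, which supplies NADPH (-0.81 ± 0.13, adjusted p = 0.0012), Acly (-0.81 ± 0.18), elovl6 (-0.77 ± 0.14) and mid1ip1b (-1.16 ± 0.3). The camera test gave adjusted p = 1.7e-05, and adjusted p = 0.12 with an estimated correlation. Of 21 lipid transport genes 6 fell and 2 rose (9 and 2 adjusted over the list alone). Falls included mfsd2ab, a homolog of the carrier of DHA-containing lysophospholipids (-0.69 ± 0.12, adjusted p = 0.0014), and the apolipoprotein gene Apob (-0.51 ± 0.13); SLC27A1, a fatty acid transporter, rose (1.1 ± 0.26). Camera gave adjusted p = 0.0017 for this list, and adjusted p = 0.21 with an estimated correlation. Of 9 genes for long-chain polyunsaturated fatty acid synthesis 3 fell (hacd3, -0.36 ± 0.1; ELOVL1, -0.34 ± 0.09; TECR, -0.34 ± 0.1) and hsd17b12a rose (0.37 ± 0.1), with 5 and 1 adjusted over the list alone. The desaturase fads2 stood at -0.05 ± 0.13 (adjusted p = 0.87). Of 18 fatty acid oxidation genes 3 fell (3 adjusted over the list alone), including decr2 (-0.55 ± 0.08) and the regulator PPARG (-0.64 ± 0.15); camera gave adjusted p = 0.016, and adjusted p = 0.33 with an estimated correlation.

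Gut and liver genes also fell at 15 dph. Of 25 brush border genes 7 fell and 1 rose (14 and 1 adjusted over the list alone), with falls in Npc1l1, the intestinal cholesterol importer (-0.99 ± 0.15, adjusted p = 0.00073), and FABP2 (-0.81 ± 0.16) and a rise in Fabp6, an ileal bile acid carrier (0.98 ± 0.21). By camera the list had adjusted p = 4.1e-07, and adjusted p = 0.16 with an estimated correlation. The sterol exporter Abcg8 fell from 40.7 ± 11.6 to 15.9 ± 4.44 CPM (-1.35 ± 0.23, adjusted p = 0.0013), and the brush border cadherin Cdhr5 (-1.6 ± 0.28) and Olfm4 (-1.43 ± 0.32) fell. Of 31 liver genes 9 fell (15 lower and 1 higher adjusted over the list alone), including VTN (-0.92 ± 0.14), the transferrin gene tf (-0.68 ± 0.16) and the bile acid enzyme CYP8B1 (-0.65 ± 0.13), with camera adjusted p = 4.1e-06 and adjusted p = 0.19 with an estimated correlation. Of 13 pancreatic enzyme genes 1 fell, the phospholipase PLA2G1B (-0.95 ± 0.24; camera adjusted p = 0.04, and adjusted p = 0.52 with an estimated correlation).

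Cell division, skeletal and muscle genes were lower in high DHA at 15 dph. Of 52 cell cycle genes 15 fell (36 adjusted over the list alone), including MAD2L1 (-0.63 ± 0.13), TOP2A (-0.56 ± 0.12) and CDC20 (-0.51 ± 0.11), with camera adjusted p = 1.4e-16 and adjusted p = 0.16 with an estimated correlation. Of 35 bone and cartilage genes 7 fell (15 adjusted over the list alone), including Acan, the gene of aggrecan (-1.43 ± 0.41), Cthrc1 (-0.81 ± 0.16), Postn (-0.78 ± 0.12) and ALPL (-0.63 ± 0.14), with camera adjusted p = 7.1e-09 and adjusted p = 0.19 with an estimated correlation. Among slow muscle and heart genes 4 of 27 fell (9 adjusted over the list alone), including nppa, a heart hormone gene (-1.09 ± 0.19), and TNNT1 (-0.52 ± 0.11); camera gave adjusted p = 7e-05, and adjusted p = 0.16 with an estimated correlation. Among fast muscle genes 4 of 32 fell (5 adjusted over the list alone), including PGAM2 (-0.69 ± 0.14); camera gave adjusted p = 8.5e-05, and adjusted p = 0.33 with an estimated correlation. Only 2 of 71 respiratory chain genes fell (0 adjusted over the list alone; median -0.2; camera adjusted p = 1.1e-08, and adjusted p = 0.49 with an estimated correlation).

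Epidermis genes were among the rises at 15 dph. Of 13 epidermis genes 4 rose (4 higher and 1 lower adjusted over the list alone): Krt17 (0.89 ± 0.11, adjusted p = 0.00016), Tp63 (0.9 ± 0.18), Evpl (0.62 ± 0.1) and PPL (0.59 ± 0.09). By camera the list had adjusted p = 0.0052, and adjusted p = 0.13 with an estimated correlation. Aloxe3, an epidermal lipoxygenase, was at 16.3 ± 1.69 CPM in low, 25.1 ± 2.78 in medium and 41.2 ± 5.55 in high DHA (1.34 ± 0.15, adjusted p = 3.8e-05). The calcium-binding S100A6 (1.33 ± 0.22) and S100A3 (1.48 ± 0.25), the chemokine Ccl28 (2.41 ± 0.37) and ZBED1 (1.37 ± 0.2) rose, as did TRIM16 (4.32 ± 0.76) and Trim25 (4.16 ± 0.73). No neuron gene passed (median 0.15; camera adjusted p = 0.0047, and adjusted p = 0.56 with an estimated correlation) and no clock gene. Without 15 dph low replicate 1, 2 or 3 there were 846, 268 and 315 changed genes, and without high replicate 2 there were 156.

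Averaged over the 3 ages, 454 genes differed between high and low DHA, 375 higher and 79 lower. Larvae of 1 level came from 3 tanks at all ages, so libraries of different ages may share a tank. The p-values of the average take all libraries as independent. Zpld1, the gene of a gel protein over inner ear hair cells, fell most (-1.68 ± 0.25, adjusted p = 0.0015): it was at 6.64 ± 1.26, 3.6 ± 2.39 and 2.03 ± 0.698 CPM in low, medium and high DHA at 10 dph and at 33.7 ± 7.92, 31.3 ± 8.93 and 16.8 ± 1.63 at 15 dph (SD, n = 3). Otol1, an otolith matrix gene, fell by 0.65 ± 0.12 on the log2 scale (SE, adjusted p = 0.0039), and CBLN2, IGSF22, Ssc4d, amdhd1 and msrb2 fell by 0.48 to 0.58. Rises included S100A3 (0.96 ± 0.17), S100A6 (0.8 ± 0.13), Tnfsf15 (0.96 ± 0.16) and Ccl28 (1.29 ± 0.3). Of 13 epidermis genes 4 rose (4 adjusted over the list alone), including Tp63 (0.61 ± 0.11) and Krt17 (0.44 ± 0.07), with camera adjusted p = 0.011 and adjusted p = 0.17 with an estimated correlation. In lipid lists Fabp6 (0.67 ± 0.13) and hsd17b12a (0.36 ± 0.06, adjusted p = 0.0021) rose and FABP2 fell (-0.43 ± 0.09). Camera called 13 lists, of which epidermis and neuron genes were higher (neuron 3 of 40 rose, median 0.16, adjusted p = 0.0012; adjusted p = 0.63 with an estimated correlation). The other 11 were lower. Among them were cell cycle (median -0.11, adjusted p = 2e-06, no member passing), lens (-0.33, 1.5e-05, none passing) and fast muscle genes (-0.11, 0.00012, 1 of 32 fell), each with adjusted p = 0.53 with an estimated correlation. Slow muscle and heart genes (-0.12, 1e-05, 2 of 27 fell) had adjusted p = 0.17 with an estimated correlation, and respiratory chain genes (-0.06, 1.9e-05, none passing) adjusted p = 0.65 with an estimated correlation. None of the 13 kept its call with an estimated correlation. An additive model with 1 difference for all ages called 24 genes. The count was 238, 65 and 276 without 5 dph low replicate 1 and high replicates 2 and 3; 890, 225, 301, 173 and 828 without 10 dph low replicates 1, 2 and 3 and high replicates 2 and 3; and 853, 253, 276, 278 and 190 without 15 dph low replicates 1, 2 and 3 and high replicates 1 and 2.

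The test across all 3 DHA levels also took libraries that may share a tank as independent. By this test 17 genes had a trend per doubling of rotifer DHA, 13 upward and 4 downward. They included cyp27c1, which makes vitamin A2 (0.16 ± 0.02 per doubling, adjusted p = 0.0011) and was at 25 ± 1.01, 28.7 ± 1.69 and 34.9 ± 3 CPM in low, medium and high DHA at 15 dph (SD, n = 3). The neuropeptide gene NPFF (0.26 ± 0.05), Smu1 (0.31 ± 0.06), TRIM16 (1.35 ± 0.26) and Trim25 (1.26 ± 0.24) had upward trends. The 4 downward trends were those of Zpld1 (-0.61 ± 0.1, adjusted p = 0.012), CBLN2 (-0.23 ± 0.05), Ssc4d (-0.21 ± 0.04) and Otol1 (-0.26 ± 0.06). Within 5, 10 and 15 dph alone 3, 0 and 255 genes had a slope, and none of the 9 genes named here passed within 5 or 10 dph. On a linear DHA scale 4 genes passed, DESeq2 called 63, and the length score as a covariate gave 34. The count was 8 and 5 without 5 dph low replicate 3 and high replicate 2; 6, 3, 7, 27, 30 and 2 without 10 dph low replicates 1, 2 and 3, medium replicate 1 and high replicates 1 and 2; and 3, 3, 10, 2, 2 and 10 without 15 dph low replicates 2 and 3, medium replicate 2 and high replicates 1, 2 and 3.

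Medium DHA was compared with both other levels to place the dose of each change. At 5 dph medium and low DHA differed in 1980 genes, 1220 higher and 760 lower in medium. Of 71 respiratory chain genes 68 rose (69 adjusted over the list alone; median 0.48), 82 of 121 ribosomal protein rows rose (82 adjusted over the list alone), none of them prey-like, and of 40 neuron genes 27 fell and 1 rose (31 and 1 adjusted over the list alone), Map2 changing by -1.14 ± 0.22 (SE). Camera gave these lists adjusted p = 9.1e-24, 3.9e-16 and 3.3e-10, each with adjusted p = 0.77 with an estimated correlation. Metabolic genes hpd (0.72 ± 0.1) and ldhba (0.83 ± 0.13) and the ribosomal gene rps29 (0.82 ± 0.13) rose; ADGRF5 (-0.97 ± 0.17), NFE2L1 (-0.71 ± 0.13) and Sfpq (-0.62 ± 0.11) fell. The length score was 0.95 lower in medium than in low DHA, and with it as a covariate 0 genes passed in edgeR. The short genes of the score are these 71 respiratory chain genes and 82 ribosomal rows. Their rise alone lowers the score, so the lost calls cannot tell a length effect from that rise. Without 5 dph medium replicate 2 there were 0 changed genes, and without low replicate 1, 2 or 3 there were 1234, 937 and 967.

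At 10 dph medium and low DHA differed in 2546 genes, 1770 higher and 776 lower in medium. Neuron genes rose (33 of 40, 2 fell; 33 and 3 adjusted over the list alone), including the glutamate receptor gene GRIN1 (1.38 ± 0.23, SE), and 15 of 26 phototransduction genes rose (18 adjusted over the list alone), including PDE6C (0.68 ± 0.12) and IMPG1 (0.87 ± 0.15). Of 52 cell cycle genes 28 fell (29 adjusted over the list alone), including the replication gene CDC6 (-1.31 ± 0.26), and of 35 bone and cartilage genes 14 fell and 1 rose (14 and 1 adjusted over the list alone), including FGFBP2 (-1.73 ± 0.32), Col9a2 (-1.1 ± 0.23) and EPYC (-1 ± 0.17). Camera gave these 4 lists adjusted p = 4.4e-10, 0.00014, 9.6e-10 and 7.7e-07, and for each the adjusted p = 0.49 with an estimated correlation. Other changes were pssA (1.71 ± 0.19, adjusted p = 2.5e-05), the protease gene Capn7 (1.05 ± 0.13), Vwa7 (0.94 ± 0.11), the galectin LGALS3 (-1.1 ± 0.16), MYL5 (-1.43 ± 0.23) and ins (-0.78 ± 0.12). Immune genes Cd74 (1.15 ± 0.17) and CSF3R (0.92 ± 0.17) rose. With the length score as a covariate 1223 genes changed, 929 of them among the 2546; 7 neuron genes then rose and 1 fell, 9 phototransduction genes rose, and 20 cell cycle and 19 bone and cartilage genes fell. All 64 prey-like rows were among the rises.

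At 15 dph medium and low DHA differed in 5 genes: the protease PRSS8 (0.74 ± 0.11, SE, adjusted p = 0.0071) and Krt17 (0.64 ± 0.11) rose, and the slow myosin Myh7 (-0.6 ± 0.1), POL (-1.09 ± 0.21) and GVINP1 (-2.64, chosen after its values were seen) fell. Camera called 10 lists, 4 higher and 6 lower in medium, but 0 with an estimated correlation, and fry called 0. With the length score as a covariate the sterol median was -0.2, with no sterol gene passing. DESeq2 called 21 genes, a fit to the compared groups alone 0, and a block of treatment label numbers 2. The count was 9, 3 and 10 without low replicates 1, 2 and 3, and 2 and 0 without medium replicates 1 and 2.

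High and medium DHA differed at 5 dph in 0 genes by edgeR, with 1417 at unadjusted p under 0.05 and 232 by DESeq2. The smallest p belonged to Niban2 (0.65 ± 0.12, SE), rhcg2 (0.68 ± 0.13) and Bnip3 (-0.6 ± 0.11), each with adjusted p = 0.07. Adjusted over the list alone, 16 of 22 sterol genes were higher in high DHA (median 0.48; camera adjusted p = 1.9e-11, and adjusted p = 0.53 with an estimated correlation) and 112 of 121 ribosomal protein rows lower (median -0.47; camera adjusted p = 1.7e-31, and adjusted p = 0.53 with an estimated correlation). The median was -1.32 for the prey-like rows and -0.44 for the other ribosomal rows, and with the length score as a covariate it was -0.14 for all 121. The score is built in part from these other ribosomal rows, so the list cannot be judged with it. Fry called 0 lists in this comparison. Without medium replicate 3 there were 730 changed genes, and without high replicate 3 there was 1. At 10 dph 10 genes differed, 4 higher and 6 lower, including pssA (-1.48 ± 0.18, adjusted p = 0.00024), the chemerin receptor CMKLR1 (-0.77 ± 0.14), LACTBL1 (-0.45 ± 0.08), act3 (1.01 ± 0.2), the complement factor Cfi (0.88 ± 0.17) and ABRA (0.76 ± 0.15). Adjusted over the list alone, 22 of 35 bone and cartilage genes were higher (median 0.48; camera adjusted p = 2e-15, and adjusted p = 0.41 with an estimated correlation), and none over all genes. DESeq2 called 133 genes, the length score as a covariate gave 110, and the count was 345, 1 and 4 without medium replicates 1, 2 and 3 and 2, 16 and 1 without high replicates 1, 2 and 3.

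At 15 dph high and medium DHA differed in 1234 genes, 572 higher and 662 lower in high DHA. Cell cycle genes fell (28 of 52; 38 adjusted over the list alone), as did 25 of 71 respiratory chain genes, with 1 rise (38 and 1 adjusted over the list alone), 10 of 22 sterol genes (14 adjusted over the list alone), and 8 of 32 fast muscle genes (9 adjusted over the list alone), including PGAM2 (-0.93 ± 0.14, SE). Camera gave adjusted p = 8.3e-15, 1.1e-12, 3e-06 and 0.00026 for these lists, and for each the adjusted p = 0.64 with an estimated correlation. CAPN2, a calpain (0.87 ± 0.1, adjusted p = 6.9e-05), ZNF395 (0.86 ± 0.1) and NCOA7 (0.6 ± 0.08) rose, and STOM (-0.92 ± 0.13), Uap1 (-0.66 ± 0.08) and the heme pathway gene BLVRB (-0.99 ± 0.13) fell. Without medium replicate 1 or 2 there were 716 and 755 changed genes, and without high replicate 2 there were 439.

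**Figure D4:**
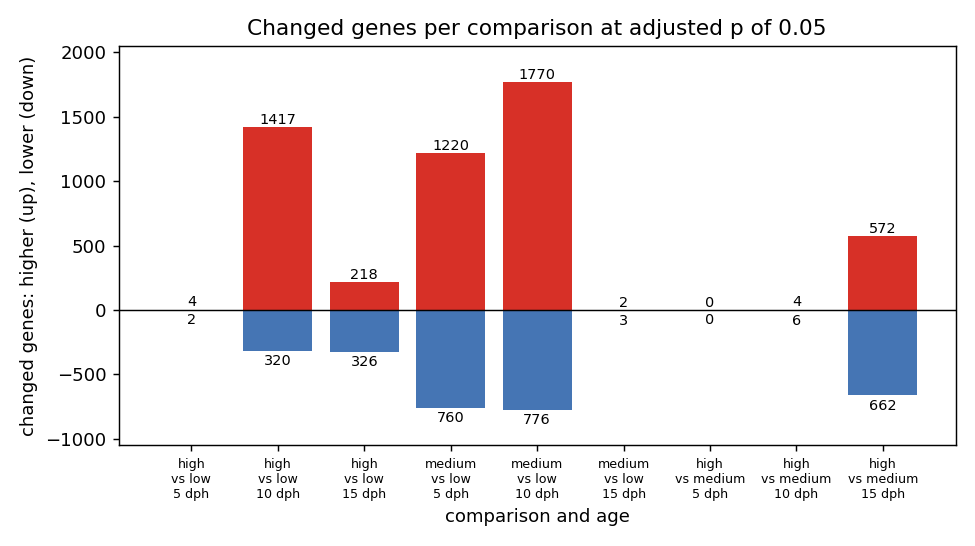
Number of changed genes (vertical; bars above 0 are higher and bars below 0 lower in the DHA level named first) in the 9 comparisons of DHA levels within an age. High with low DHA gave 6, 1737 and 544 genes at 5, 10 and 15 dph.

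Whether the high to low difference itself changed with age was tested directly. From 5 to 10 dph it changed for 1321 genes (991 toward high DHA, 330 toward low). ABRA (2.06 ± 0.23, SE, adjusted p = 3.3e-05), OTUD1 (2.19 ± 0.33), TSG101 (1.96 ± 0.28), ALPK2 (1.55 ± 0.25) and mxd1 (0.98 ± 0.15) moved toward high DHA, and the ribosome and nuclear genes NOP58 (-0.65 ± 0.12), DKC1 (-1.1 ± 0.2), KPNA2 (-1.14 ± 0.22) and RCC1 (-0.95 ± 0.18) toward low, with cetA (-1.2 ± 0.2). Of the genes that moved toward high DHA 63 were prey-like rows. With the length score as a covariate 54 genes passed, and 27 of these were ribosomal protein rows. The count was 786, 808, 413 and 94 without 5 dph low replicates 2 and 3 and high replicates 2 and 3, and 523, 807, 686 and 485 without 10 dph low replicates 2 and 3 and high replicates 1 and 2.

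From 10 to 15 dph the difference changed for 251 genes, 34 toward high DHA and 217 toward low. TSG101 (-2.25 ± 0.27, SE, adjusted p = 0.00014), the transcription factor gene CEBPD (-1.79 ± 0.3), the gut chloride exchanger Slc26a3 (-1.7 ± 0.27), ABRA (-1.42 ± 0.23) and MAMDC4 (-1.14 ± 0.15) moved toward low DHA. Herc4 (3.69 ± 0.81), Aloxe3 (1.34 ± 0.22), CAPN2 (0.72 ± 0.15), NCOA7 (0.66 ± 0.11) and the glycolytic gene PFKP (0.49 ± 0.11) moved toward high DHA. DESeq2 called 467 genes, and with the length score as a covariate 75 passed. The count was 627, 47, 140, 115, 134 and 565 without 10 dph low replicates 1, 2 and 3 and high replicates 1, 2 and 3, and 143, 148 and 122 without 15 dph low replicate 1 and high replicates 1 and 2.

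From 5 to 15 dph the difference changed for 124 genes, 39 toward high DHA and 85 toward low. The sterol genes IDI1 (-1.39 ± 0.2, SE, adjusted p = 0.0011), CYP51A1 (-1.48 ± 0.25) and msmo1 (-1.17 ± 0.19) moved toward low DHA, with MCOLN2 (-1.36 ± 0.21). Of the 22 sterol genes 18 moved toward low and none toward high DHA (21 adjusted over the list alone; median -1.18; camera adjusted p = 9.1e-23, and adjusted p = 0.14 with an estimated correlation). Aloxe3 (1.78 ± 0.23, adjusted p = 0.00052), CAPN2 (0.98 ± 0.15), TNS1 (0.97 ± 0.18), Oaz2 (0.73 ± 0.14) and NCOA7 (0.65 ± 0.12) moved toward high DHA. DESeq2 called 364 genes, and DESeq2 size factors in edgeR gave 73 toward high and 81 toward low. The count was 66, 44, 68, 39 and 11 without 5 dph low replicates 1, 2 and 3 and high replicates 2 and 3, and 491, 54 and 51 without 15 dph low replicates 1 and 2 and high replicate 2.

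Ages were compared over all DHA levels. Age goes with the sampling occasion, so development cannot be told apart from other differences between occasions. From 5 to 10 dph 4227 genes changed, 1947 higher and 2280 lower at 10 dph. The trypsin gene Prss1 rose most (4.87 ± 0.33, SE, adjusted p = 3.6e-10), and COL10A1, the collagen of hypertrophic cartilage (2.75 ± 0.1, adjusted p = 6e-15), C1QL2 (2.98 ± 0.15) and LOXL4 (2.8 ± 0.13) rose. Retsat, a retinol saturase (-2.55 ± 0.14), klhl38 (-2.12 ± 0.19), the otolith matrix gene otomp (-1.91 ± 0.25), SLC2A11 (-1.9 ± 0.18) and the muscle ubiquitin ligase FBXO32 (-1.73 ± 0.14) fell. Of 22 sterol genes 20 rose and 2 fell (20 and 2 adjusted over the list alone), FDPS by 1.6 ± 0.12; 44 of 52 cell cycle genes rose (45 adjusted over the list alone); and of 32 fast muscle genes 21 rose and 3 fell (21 and 3 adjusted over the list alone), including CASQ1 (2.15 ± 0.11) and ENO3 (1.69 ± 0.12). Camera gave adjusted p = 1.1e-10, 2e-12 and 1.1e-08 for these lists, and for each the adjusted p = 0.36 with an estimated correlation.

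Other lists changed from 5 to 10 dph as well. Of 35 bone and cartilage genes 17 rose and 2 fell (17 and 2 adjusted over the list alone), including Panx3 (2.02 ± 0.08, SE), with camera adjusted p = 0.00055. Of 40 neuron genes 31 fell and 2 rose (32 and 2 adjusted over the list alone), with camera adjusted p = 1.9e-05; both lists had adjusted p = 0.65 with an estimated correlation. Of 9 genes for long-chain polyunsaturated fatty acid synthesis 6 rose (6 adjusted over the list alone), including fads2 (0.5 ± 0.08, adjusted p = 1.2e-05) and ACSL6 (0.64 ± 0.07), with camera adjusted p = 0.024 and adjusted p = 0.36 with an estimated correlation. Liver genes rose (14 of 31, 5 fell; 14 and 5 adjusted over the list alone), including CYP8B1 (1.91 ± 0.09), and 19 of 34 heat shock genes rose and 7 fell (19 and 7 adjusted over the list alone). Both had camera adjusted p = 0.014, and adjusted p = 0.65 with an estimated correlation. All 64 prey-like rows fell.

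From 10 to 15 dph 4208 genes changed, 2317 higher and 1891 lower at 15 dph. Ribosomal and respiratory chain genes fell together: 104 of 121 ribosomal rows fell (105 adjusted over the list alone; median -0.53) and 66 of 71 respiratory chain genes (67 adjusted over the list alone; median -0.29). Without the prey-like rows 81 of 82 ribosomal rows fell. Camera gave adjusted p = 6.6e-24 and 9.1e-16, and for both the adjusted p = 0.68 with an estimated correlation. The mean length score was higher at 15 than at 10 dph in each DHA group, and with it as a covariate 2472 genes changed, 1931 of them among the 4208. With it 24 ribosomal rows fell, and 10 respiratory chain genes fell and 3 rose (medians -0.14 and -0.03). The 153 short genes of the score are the 71 respiratory chain genes and the 82 ribosomal rows themselves, so these lists cannot be judged with it. Large falls were those of klhl38 (-4.02 ± 0.29, SE), the muscle ubiquitin ligase TRIM63 (-3.15 ± 0.24), the glucose-6-phosphatase rows G6PC1 (-2.19 ± 0.11) and g6pc1 (-2.11 ± 0.12), Ucp2 (-1.98 ± 0.16) and PDK2 (-1.91 ± 0.22). The mucus gene FCGBP (3.82 ± 0.34), Zpld1 (2.84 ± 0.2, adjusted p = 5.6e-10), Prss1 (2.43 ± 0.24) and the amino acid transporter Slc6a18 (2.21 ± 0.15) rose.

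Among organ lists from 10 to 15 dph, 17 of 25 brush border genes fell and 2 rose (18 and 2 adjusted over the list alone), including the lactase gene LCT (-1.14 ± 0.11, SE) and the alkaline phosphatase ALPI (-0.91 ± 0.09). Of 35 bone and cartilage genes 17 fell (16 adjusted over the list alone), of 13 pancreatic enzymes 8 fell and 1 rose (10 and 1 adjusted over the list alone), of 21 lipid transport genes 10 fell (10 adjusted over the list alone), and of 10 glia genes 5 fell (5 adjusted over the list alone). Sterol genes rose (14 of 22, 1 fell; 15 and 1 adjusted over the list alone), as did 28 of 52 cell cycle genes, with 4 falls (28 and 4 adjusted over the list alone). Camera called these 7 lists at adjusted p between 0.00017 and 0.027, and for each the adjusted p = 0.68 with an estimated correlation. Of 40 neuron genes 20 rose and 3 fell (20 and 3 adjusted over the list alone; camera adjusted p = 0.027, and adjusted p = 0.76 with an estimated correlation), and 1 rose and 10 fell with the length score as a covariate. With that score 4 lipid transport genes fell and 1 rose, 5 pancreatic enzymes fell and 1 rose, 12 brush border, 18 bone and cartilage and 5 glia genes fell, 9 sterol genes rose, and 21 cell cycle genes rose and 3 fell. Of 16 clock genes 7 rose and 8 fell (7 and 8 adjusted over the list alone), with NR1D1 at -2.73 ± 0.2, Ciart at -1.7 ± 0.14, RORB at 1.44 ± 0.11 and BMAL1 at 1.18 ± 0.1. A shift of clock phase between the sampled ages was not tested.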

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

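All 9 tests of explanations in this part were chosen after the results were seen; the counts over other splits of the libraries were planned. The difference between high and low DHA changed with age, by a test of that change itself, for 1321 genes from 5 to 10 dph, 251 from 10 to 15 dph and 124 from 5 to 15 dph. For the sterol synthesis list the change from 5 to 15 dph had a camera p = 3.2e-24 (p = 0.0051 with an estimated correlation, adjusted p = 0.14).

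At 10 dph 1737 genes differed between high and low DHA. Prey RNA is argued against as the cause of most of the 1367 rises outside the prey-like rows: prey-like rows were higher in low than in high DHA at 5 dph, by 2.36 times their CPM difference at 10 dph, but these rises had a median ratio of 0.327 (quartiles 0.00468 and 0.621). A loss of long transcripts, from RNA quality or fragment length, stays open: with the length score, chosen after long and short genes were seen to differ, as a covariate 4.03% of the calls were kept, since the median absolute change of the called genes went from 0.61 to 0.35 with a standard error of 0.16 and then 0.17, while 99.9% of them kept their sign. That low DHA larvae were further along in development stays open too, as the changes correlated at -0.51 with those from 5 to 15 dph across genes, which are not independent replicates. With the score as a covariate in the 10 dph comparison alone the correlation was -0.58, so it did not rest on the score difference at 10 dph. Very long genes had a median of 0.01 from 5 to 15 dph, but the mean score was higher at 15 than at 5 dph in each DHA group. The score was not taken out of the change from 5 to 15 dph. A shift of clock phase cannot be told apart, since 6 clock genes of the NR1D1 arm had a median of 1.07 but BMAL1, CLOCK and NPAS2 had one of -0.19, between the values set for and against it; an effect of DHA itself stays open as untested.

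Sterol synthesis genes stood above low DHA at 5 dph (median 0.48) and below it at 15 dph (-0.61) in high DHA larvae. At 5 dph alone no sterol gene passed over all genes, and fry called 0 of the 28 lists. A shift of all genes is excluded, since the sterol genes changed from 5 to 15 dph by a median of -1.14 less the median of all genes (quartiles -1.33 and -0.93), a difference that no factor per library alters. The change exceeded the spread between these libraries, with the larger of the camera and fry p at 1.7e-05 (fry adjusted p = 0.00047). The camera p of this same change flagged the pattern, so the test is no independent evidence against replicate error. With an estimated correlation the camera comparison with other genes gave adjusted p = 0.14, and the 5 dph high group held 2 libraries. Whether high DHA larvae were at another stage stays open: the changes at 15 dph correlated at -0.29 across genes with those from 5 to 10 dph, just short of the value set for it. An effect of DHA that depends on age stays open as untested.

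The 16 low-count rows with fly-style ribosomal names summed to at most 2.48 CPM per library in 10 dph low DHA and 3.08 at 15 dph, except for 6.33 in 15 dph high replicate 3, close to the 7.58 of 10 dph high replicate 2. The median log2 change of these rows from 5 to 10 dph differed by -2.66 from that of the other ribosomal rows. This restates the pattern, so it sets aside only larval paralogs with the same course as those rows. Larval paralogs with a course of their own stay open. RNA of 1 other organism in the gut, such as the rotifer prey, stays open: the rows kept close to 1 ratio over the 9 groups, with a chi-square of 1.32 per degree of freedom, but sets of abundant ribosomal rows at the same depth gave 0.869 to 1.48, so this test does not separate prey RNA from larval RNA. No biological difference of the larvae themselves was tested for this pattern.

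Other splits of the same libraries were counted for DHA levels within an age where both groups held 3 libraries, and for the average, the ages, the trend and the change of the DHA difference from 10 to 15 dph. The average, 10 with 5 dph and the trend include the 5 dph high group of 2; comparisons of that group within 5 dph and the changes of the DHA difference from 5 dph were not split. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real and the highest other counts were 1737 and 768 for high with low at 10 dph, 544 and 63 at 15 dph, 1980 and 0 for medium with low at 5 dph, 2546 and 5 at 10 dph, 5 and 8 at 15 dph, 10 and 316 for high with medium at 10 dph, and 1234 and 3 at 15 dph. The split with 768 set low replicate 1 and high replicates 1 and 2 against the rest and parted the libraries by 0.71 in length score, against 0.67 for the real split. For 5 genes at 15 dph and for 10 genes at 10 dph, 2 of the 10 splits gave as many, and the 316 genes point to a structure among the 10 dph medium and high libraries, medium replicate 1 and high replicates 1 and 2 against the rest. Of 100 drawn splits only the real 1 reached 454 genes for the average (highest other 256), 4227 for 10 with 5 dph (3467), 4208 for 15 with 10 dph (1968) and 17 for the trend (8), which excludes chance if the libraries are independent. Larvae of 1 level came from 3 tanks at all ages, so for the average and trend the libraries may not be independent. Splits of whole tanks were not counted; for the average there would be 10, too few for a share under 0.05. For the change from 10 to 15 dph 4 of 100 reached 251 genes, a share so near 0.05, from drawn splits, that chance is not firmly excluded; 1 of the others gave 1152, which points to a structure of the samples apart from the groups.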

How the results depend on the processing

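The covariate, prey-like, identical-row and lowest-TMM alternatives and the list tests in comparisons with medium DHA were chosen after the data were seen; the others were planned. Counts not named here stayed within 1.5 times of the reported value. For those that moved the cause was not tested, except where the setting itself took away genes or libraries. The planned result on internal controls was not run, as they have no count column. Counts are listed as high with low, then medium with low, then high with medium DHA.

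Requiring an absolute log2 fold change of at least 1 left 0, 249 and 48 genes at 5, 10 and 15 dph for high with low, 75, 613 and 2 for medium with low, 3 at 10 and 65 at 15 dph for high with medium, 15 for the average, 307 and 161 for 10 with 5 and 15 with 10 dph, 410, 108 and 44 for the changes from 5 to 10, 10 to 15 and 5 to 15 dph, and 3 for the trend. DESeq2 called 44 for high with low at 5 dph, 21 for medium with low at 15 dph, 232 and 133 for high with medium at 5 and 10 dph, 467 and 364 for the changes from 10 to 15 and 5 to 15 dph, and 63 for the trend. A fit to the compared groups alone gave 1951, 381 and 163 for high with low at 5, 10 and 15 dph, 854 and 0 for medium with low at 5 and 15 dph, and 5 for high with medium at 10 dph. With title numbers as a block there were 10 for high with low at 5 dph and 2 and 16 for high with medium at 5 and 10 dph; with treatment label numbers there were 2 for medium with low at 15 dph and 1 for high with medium at 5 dph. At a mean CPM of at least 10 there were 6 for high with medium at 10 dph and 146 for the change from 10 to 15 dph. The additive model gave 24 for the average, and a linear DHA scale gave 4 for the trend; slopes within 5, 10 and 15 dph gave 3, 0 and 255. With DESeq2 size factors high with low at 5 dph gave 2 higher and 2 lower in place of 4 and 2, and the change from 5 to 15 dph 73 and 81 in place of 39 and 85. All 6 counts of shifted lists (7, 4 and 18 for high with low at 5, 10 and 15 dph, 13 for the average, 8 and 10 for the ages) became 0 with an estimated correlation.

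With the length score as a covariate there were 3 and 71 for high with low at 5 and 10 dph, 0 and 1223 for medium with low at 5 and 10 dph, 110 for high with medium at 10 dph, 2472 for 15 with 10 dph, 54 and 75 for the changes from 5 to 10 and 10 to 15 dph, and 34 for the trend. Without 5 dph medium replicate 2 and 10 dph low replicate 2 there were 678 for high with low at 10 dph, 396 for medium with low at 5 dph, 21 for high with medium at 10 dph, 211 for the average, and 88 and 319 for the changes from 10 to 15 and 5 to 15 dph. With the score, named genes that changed sign were, for medium with low at 5 dph, ANXA2 (0), Ank1 (0.06), Ephx1 (-0.02), FABP6 (-0.12), HGD (-0.07), Mef2d (0.13), Nfkbia (-0.03), RYR3 (0.19), Rora (0.08), TNNI2 (-0.03), mt-co1 (-0.01), nr3c1 (0.12), thra (0.16) and thrb (0.03), for medium with low at 10 dph txn (0.02), and for 15 with 10 dph EPB41 (-0.06) and mt-co1 (0), none of which passed. Of the other named-gene results with the score, 552 kept their call and 228 lost it, and with DESeq2 792 kept it and 2 lost it. The lists were not tested as sets with the score or with DESeq2. Of named-gene and list results without the lowest-TMM libraries, 718 kept their call and 139 lost it.

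Leaving out 1 library at a time gave 0 to 5 (high with low at 5 dph), 428 to 2069 (10 dph), 156 to 846 (15 dph), 0 to 2839 (medium with low at 5 dph), 2149 to 2505 (10 dph), 0 to 10 (15 dph), 0 to 730 (high with medium at 5 dph), 1 to 345 (10 dph), 439 to 1005 (15 dph), 65 to 890 (average), 3769 to 4379 and 3949 to 4272 (ages), 94 to 1868, 47 to 627 and 11 to 491 (changes from 5 to 10, 10 to 15 and 5 to 15 dph) and 2 to 30 (trend). Lists called ranged from 5 to 8, 3 to 5 and 14 to 18 for high with low at 5, 10 and 15 dph, 11 to 15 for the average, and 8 to 9 and 9 to 13 for the ages. Depth limited few genes: 91 tested rows had a mean under 1 CPM.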

Other observations

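Smaller lists gave few changes between high and low DHA at 15 dph. Of 22 antioxidant genes 3 fell and 1 rose (4 and 1 adjusted over the list alone): GPX4, which repairs lipid peroxides (log2 fold change -0.52 ± 0.12, SE), sod1 (-0.49 ± 0.11), TXNRD1 (-0.69 ± 0.2) and msrb1 (0.74 ± 0.17). Camera gave adjusted p = 0.007, and adjusted p = 0.39 with an estimated correlation. Of 5 stomach genes the chitinase gene Chia fell (-0.5 ± 0.1), and of 11 myogenic regulators EYA2 rose (camera adjusted p = 0.047, and adjusted p = 0.5 with an estimated correlation). Of 14 lens genes 1 fell (camera adjusted p = 0.016, and adjusted p = 0.55 with an estimated correlation), as did 1 of 26 phototransduction genes and 1 of 9 erythrocyte genes. Of 6 eicosanoid genes 1 rose, and 1 rose and 1 fell of 17 immune and of 10 glia genes. No growth and endocrine gene of 18 passed, no heat shock gene of 34, no ribosomal protein row of 121 (camera adjusted p = 0.032, and adjusted p = 0.77 with an estimated correlation) and neither of the 2 mitochondrially encoded genes.

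At 10 dph the immune list held changes of both signs in high over low DHA. C3 (0.48 ± 0.14, SE), lcp1, a leukocyte actin bundler (0.46 ± 0.13), IRF8 (0.65 ± 0.22), MPEG1 (0.6 ± 0.21) and CSF3R (0.5 ± 0.17) rose, and the interferon-stimulated DHX58 (-0.98 ± 0.35) and rsad2 (-3.13 ± 0.76) fell, rsad2 with a wide spread in low DHA (8.58 ± 9.34 CPM, SD, n = 3). At 15 dph DHX58 (1.15 ± 0.35) and Usp18 (1.19 ± 0.37), also interferon-stimulated, rose. Of 13 epidermis genes 4 rose at 10 dph (4 adjusted over the list alone), Tp63 by 0.84 ± 0.19. With the length score as a covariate no immune or epidermis gene passed at 10 dph, while the list medians were 0.3 for immune (0.06 without the score) and 0.14 for epidermis genes (0.17 without it). From 10 to 15 dph the pepsinogen row PGA rose over all DHA levels (6.32 ± 2.49, adjusted p = 0.039), but it rested on medium DHA at 15 dph, with 55.9 ± 87.8 CPM (SD, n = 3), and its adjusted p was 0.87 with the length score as a covariate. Of 11 myogenic regulators 3 rose and 2 fell from 5 to 10 dph, and 5 rose and 4 fell from 10 to 15 dph (the same counts adjusted over the list alone). Among them myod1 changed by 0.62 ± 0.09 from 5 to 10 dph and by -0.83 ± 0.09 from 10 to 15 dph, and mymk, a myoblast fusion gene, by 0.49 ± 0.12 and -0.63 ± 0.12.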
